A study of Mus musculus with 25 samples.

How the data were processed

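Messenger RNA was sequenced from 25 mouse samples of tumours and healthy colon epithelium. Per the labels, 10 were macrodissected colon tumours induced by AOM-DSS (the carcinogen azoxymethane followed by the colitis-inducing agent dextran sulfate sodium), 9 were macrodissected tumours of an APC-KRAS genetic model, and 6 were epithelial cells released from healthy colon with EDTA. In each tissue, knockout mice carried loxP-flanked Bcl9 and Bcl9l alleles together with Vil-Cre, a recombinase driven by the villin promoter and active in gut epithelium. Wild-type mice carried the same floxed alleles without Cre. The APC-KRAS mice additionally carried the APC-1638N allele and a villin-driven mutant Kras transgene. RNA was purified with NucleoSpin RNA columns and libraries were made with a strand-preserving TruSeq mRNA kit, per the labels' protocols.

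The deposited values were raw counts, that is whole numbers of reads per gene symbol, with no normalization by the authors. The submitters' processing notes name CASAVA 1.82 and the mouse build GRCm38 (mm10). The aligner, the counting program, its strand setting, its treatment of reads that map to several places and the gene annotation are not given in the sources used here. Each library listed 38924 features, of which 13208 had no read in any library and 480 carried a number added to a repeated symbol. Of the symbols, 35529 were found in the GENCODE annotation of GRCm38, which supplied the coordinates. Tsix, transcribed antisense to Xist, reached at most 21 counts in any library, whereas Xist had 554 to 4244 counts in the libraries where it exceeded the Y-linked gene Ddx3y. Genes of near-identical families (Mptx1 and Mptx2, the Cyp2c, Defa and H2 genes, the beta globins) could exchange reads, so their values are uncertain.

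Library totals ran from 25152131 to 105860869 counts. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 38.07, between a pair of AOM-DSS wild-type libraries. The labels number tumours and extracts without saying that each came from a separate animal, and 3 knockout libraries of the APC-KRAS model are named 32_1a, 32_1b and 32_2a. The p-values therefore measure the spread between these samples, which in part may be a spread between tumours of 1 mouse.

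Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts for their design were removed with filterByExpr, library sizes were scaled with TMM factors, and a robust quasi-likelihood model (glmQLFit, glmQLFTest) was fitted. Each knockout effect was estimated from the libraries of its own tissue. Differences between knockout effects, and the contrasts of wild-type tumours with wild-type healthy epithelium, came from 1 model over all 6 groups. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. All edgeR tests were two-sided. Log2 fold changes are knockout minus wild type and are given with their standard error (SE). CPM values, which are counts divided by the library total and scaled to a common total, were computed with TMM factors over all 25 libraries, and a pseudocount of 0.5 CPM was added in the plots per gene. Principal components used log2 CPM with a prior count of 2.

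A set of 32 gene lists covered Wnt and other signalling pathways, epithelial cell types, regional identity, non-epithelial cell types, inflammation and technical signs. The lists held 505 genes, of which 494 were in the files. The lists were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera was repeated with an estimated correlation. Of all list calls in the 8 comparisons, the estimated correlation kept 1, that of the regenerative and fetal-like list in APC-KRAS tumours against healthy epithelium. Members past the threshold were counted over all genes tested and again adjusted over the list alone.

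In each knockout comparison Bcl9 and Bcl9l were named first. Among genes past the threshold with an average log2 CPM of at least 1, the 10 largest rises and 10 largest falls were taken (5 and 5 in the other comparisons). Immunoglobulin and T cell receptor segments and unnamed gene models were left out and counted as groups. Up to 4 members past the threshold with the smallest p were taken from each list, or up to 2 as values where none passed. Members of a comparison's list were described only where they were in this set, and most genes of the set whose call ended when a single library was left out were not described. Values of genes shared between tissues were chosen after the data were seen, as were the genes named to illustrate them. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

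Alternatives comprised RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with sample quality weights, 1 fit of all 6 groups, removal of Xist and Y-linked genes, a stromal and immune index as covariate, a regional index (small intestine minus distal colon genes) as covariate in APC-KRAS tumours, a replicate block, sums of the 32-series libraries, and each library left out in turn. Removal of mitochondrial genes, of AOM-DSS knockout tumours 3 and 5, and of APC-KRAS wild type 17 with 32_1a, and a fibroblast and endothelial index as covariate, were added after the data were seen.

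The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed and 3 repeats. Changes of 4-fold were recovered for 82.67% of genes in the AOM-DSS comparison (17131 genes), 58.33% in the APC-KRAS comparison (16077 genes) and 85.33% in healthy epithelium (16870 genes). Changes of 2-fold were recovered for 43.67%, 3.33% and 32.33%. False calls made up 3.29%, 5.59% and 10.47% of calls, respectively. For the differences between knockout effects, 4-fold changes were recovered for 50.0% (AOM-DSS minus healthy), 52.33% (APC-KRAS minus healthy) and 62.33% (AOM-DSS minus APC-KRAS). These shares hold for the simulated spread only. In real healthy epithelium 3242 genes had an unadjusted edgeR p under 0.05 and 3 passed. Lgr5, with a log2 change of -3.01, did not pass (edgeR adjusted p = 0.0908). Recovery in the real healthy libraries may thus be lower.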

Results

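The series compared gene expression between mice with and without intestinal Bcl9 and Bcl9l in 3 tissues. BCL9 and BCL9L are co-activators that bind beta-catenin and carry its signal to target genes of the Wnt pathway. AOM-DSS tumours comprised 5 knockout and 5 wild-type libraries, APC-KRAS tumours 4 and 5, and healthy colon epithelium 3 and 3. Library totals were 25152131 to 47711418 counts in AOM-DSS tumours, 26422795 to 42687686 in APC-KRAS tumours and 65622963 to 105860869 in healthy epithelium. Between 19267 and 21982 genes were detected per library.

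The first principal component took 45.89% of the variance and the second 14.44%. Healthy epithelium lay at one end of the first component and AOM-DSS wild-type tumours at the other. AOM-DSS knockout tumours 3 and 5 lay apart from the other 3 on this component, at -26.98 and -1.56 against 60.14 to 79.13. The share of counts from the 37 mitochondrial genes was 7.05% ± 1.57 in AOM-DSS knockout and 6.31% ± 0.57 in wild-type tumours (SD, n = 5 and 5, exact permutation p = 0.357, two-sided). It was 20.3% ± 3.29 and 15.5% ± 5.76 in APC-KRAS tumours (n = 4 and 5, exact permutation p = 0.19, two-sided), and 15.3% ± 3.52 and 13.9% ± 0.45 in healthy epithelium (n = 3 and 3, exact permutation p = 0.8, two-sided, where 0.1 is the smallest p possible). The Y-linked gene Ddx3y exceeded Xist in 3 of 3 knockout and 2 of 3 wild-type extracts of healthy epithelium, in 1 of 5 AOM-DSS wild-type tumours, and in no other library. Sex was therefore not balanced across the groups.

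**Figure D1:**
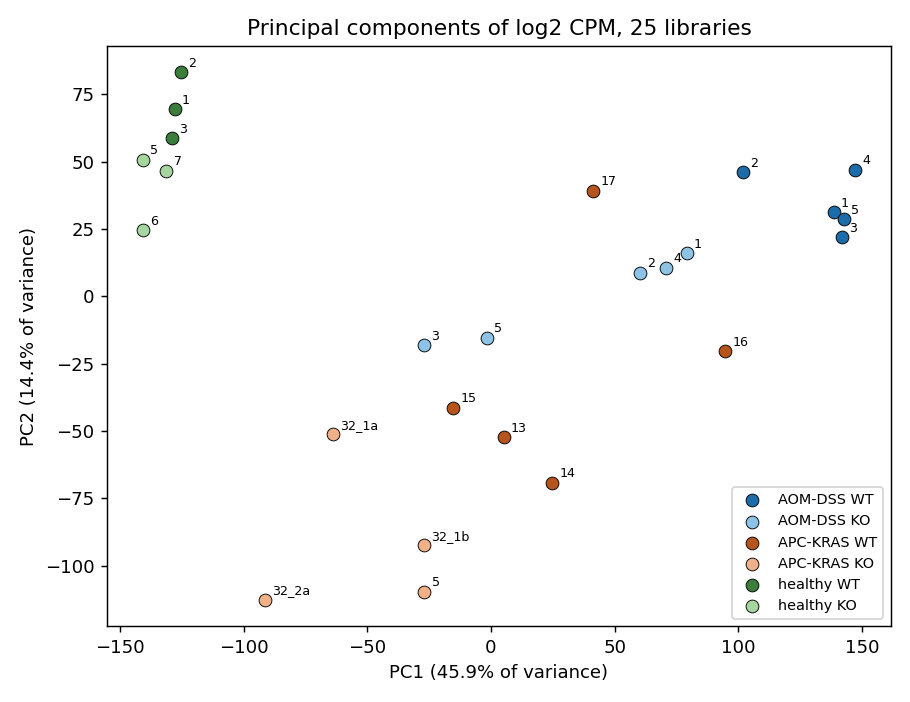
Principal components of log2 CPM for the 25 libraries, with the first component (45.89% of variance) on the x axis and the second (14.44%) on the y axis, each point being 1 library numbered as in the labels and coloured by group. AOM-DSS knockout tumours 3 and 5 lie at -26.98 and -1.56 on the first axis, and the other 3 knockout tumours at 60.14 to 79.13.

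The targeted genes were examined first. Bcl9 (GRCm38 chromosome 3, 97203662 to 97297917, minus strand) and Bcl9l (chromosome 9, 44482825 to 44511896, plus strand) were read as counts over whole genes. The deleted exons are not given in the sources used here, so counts over the rest of each gene cannot show whether the deletion took place. In AOM-DSS tumours Bcl9l was 13.4 ± 3.40 CPM in knockout and 20.3 ± 0.80 CPM in wild type (SD, n = 5 and 5) and fell by 0.67 on the log2 scale (SE 0.17, edgeR adjusted p = 0.0157). That call was lost in the fit of all 6 groups (adjusted p = 0.47, from 0.000733 to 0.47 over its alternatives). Bcl9 was not lower there: it was 61.8 ± 9.6 against 46.7 ± 3.62 CPM, with a log2 change of 0.33 (SE 0.12, adjusted p = 0.0553), which passed without knockout tumour 2 (adjusted p = 0.0332, from 0.0302 to 0.431 over its alternatives). In healthy epithelium the log2 change of Bcl9l was -1.58 (SE 0.29, adjusted p = 0.0908), from 16.7 ± 4.52 CPM in wild type to 5.58 ± 1.40 CPM in knockout (n = 3 and 3). Without wild-type library 3 that change was -1.77 and passed (adjusted p = 0.0428, from 5.05e-05 to 0.759 over its alternatives). The Bcl9 change there was -0.43 (SE 0.16, adjusted p = 0.21).

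In APC-KRAS tumours Bcl9 counts were not lower in the libraries labelled knockout, which by itself cannot show that the labels are wrong. Bcl9 was higher in the libraries labelled knockout, at 76.7 ± 7.99 CPM against 28.9 ± 8.39 CPM in wild type (SD, n = 4 and 5), a log2 change of 1.43 (SE 0.22, adjusted p = 0.00441) with all 4 libraries above all 5. The call was lost when libraries 32_1a, 32_1b and 32_2a were summed into 1 (adjusted p = 0.0506, from 1.58e-07 to 0.0506 over its alternatives). Bcl9l was 5.33 ± 4.12 and 6.62 ± 8.51 CPM, with a log2 change of -0.31 (SE 0.87, adjusted p = 0.862). Its value depended on wild-type tumour 17, at 21.4 CPM, without which the change was 0.86 (adjusted p = 0.404, from 0.404 to 0.998 over its alternatives). The counts thus leave the genotype unchecked, and these tumours are called tumours labelled knockout.

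**Figure D2:**
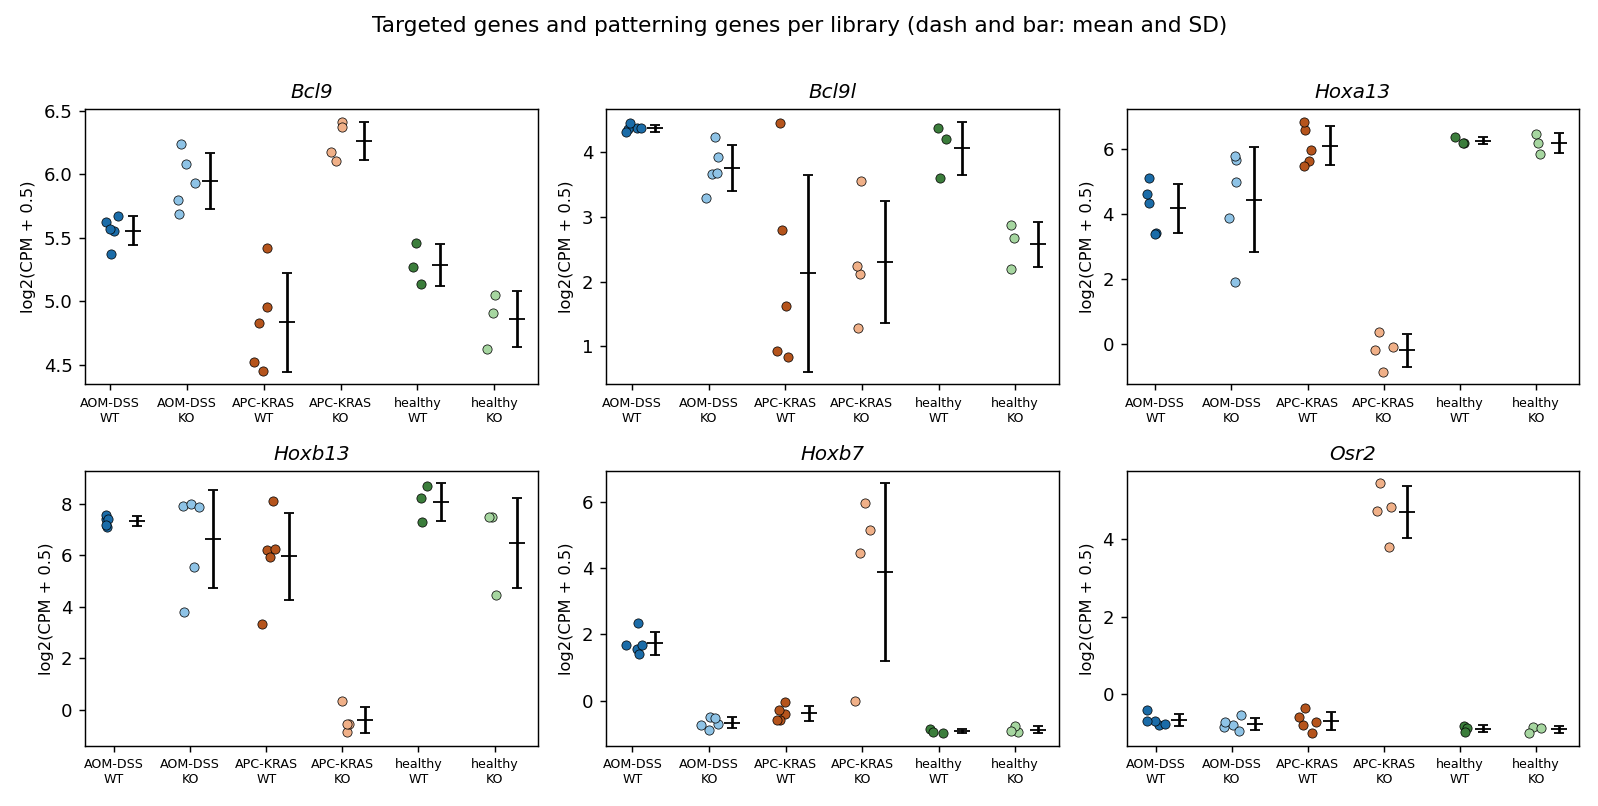
Log2(CPM + 0.5) of Bcl9, Bcl9l, Hoxa13, Hoxb13, Hoxb7 and Osr2 on the y axis in each library, by group on the x axis, where points are libraries and the dash and bar are the mean and SD of 3 to 5 libraries. Bcl9 stands higher in the APC-KRAS tumours labelled knockout (76.7 CPM on average) than in wild type (28.9 CPM), and Hoxa13 is nearly absent from the same 4 tumours (0.42 CPM).

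The knockout effect in AOM-DSS tumours was broad: the Wnt target and mesenchymal lists were lower, and the lists for epithelial genes, cholesterol synthesis and MHC class II antigen presentation were higher. Of 17131 genes tested, 4833 passed, 2366 higher and 2467 lower, among them 182 and 244 unnamed gene models. Among the largest falls, the patterning factor Gbx2 fell by 8.01 (SE 1.02, adjusted p = 0.0011), and the homeobox genes Alx3 and Irx5 fell by 6.92 and 6.80. The desmosomal cadherin Dsc3 fell by 6.96 and the GABA receptor subunit Gabra4 had a log2 change of -7.78. Svopl, a putative transporter, dropped by 7.26 (SE 0.53, adjusted p = 9.92e-05), from 76.0 ± 25.9 to 0.50 ± 0.37 CPM. Zp2, Ankfn1 and Pnliprp1 fell by 7.95, 7.17 and 6.63. Among the largest rises were the cytochrome P450 gene Cyp2c55 (log2 change 6.31, SE 1.63, adjusted p = 0.0189) and the sulfate transporter Slc13a1 (5.63, SE 1.44, adjusted p = 0.0181). Both calls were lost with limma-voom (adjusted p = 0.138 and 0.077) and without knockout tumours 3 and 5 (log2 changes 0.93 and 1.09, adjusted p = 0.208 and 0.141), with highest values of 0.372 and 0.269 over their alternatives. Btnl1 and Btnl2, butyrophilin-like genes of gut epithelium, rose by 5.14 and 4.07, the tight junction gene Cldn15 by 3.97, and the myosin Myo18b by 3.96 (SE 0.23, adjusted p = 6.22e-05). The calls of Cldn15 and Btnl1 were lost with the fibroblast and endothelial index below (adjusted p = 0.29 and 0.0743, the highest over their alternatives). The number of genes called was 3152 without wild-type tumour 3, 3135 without wild-type tumour 4 and 2782 without knockout tumours 3 and 5. With a fibroblast and endothelial index as covariate it was 633, of which 619 were among the 4833, and of the single genes followed through the alternatives 77 lost the call and 39 did not.

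Of 29 Wnt target genes tested in AOM-DSS tumours, 17 fell and 4 rose (18 and 7 adjusted over the list alone). Camera placed the list lower than other genes (adjusted p = 6.89e-06, adjusted p = 0.603 with an estimated correlation). Axin2, a negative feedback gene of the pathway (chromosome 11, 108920349 to 108950783), was 164.7 ± 17.4 CPM in knockout and 343.8 ± 46.3 CPM in wild type, a fall by 1.13 (SE 0.11, adjusted p = 0.000261). The transcription factor Sp5 fell by 4.13 (SE 0.38, adjusted p = 0.000233) and the Wnt inhibitor Apcdd1 by 6.45 (SE 0.76, adjusted p = 0.000789). Myc rose by 0.97 (SE 0.12, adjusted p = 0.000793). Of 25 intestinal stem cell genes, 7 fell and 4 rose (7 and 7 adjusted over the list alone) and the list was not called (adjusted p = 0.135). Its members Lgr5, the crypt stem cell receptor, Smoc2 and the ubiquitin ligase Znrf3 fell by 4.60, 3.79 and 1.65. Lgr5 stood at 4.01 ± 3.86 against 92.8 ± 43.9 CPM. Of the 11 genes of the BCL9-beta-catenin complex, 5 fell, including the partner Pygo1 (-3.42), Lef1 (-3.10) and Ctnnb1, which encodes beta-catenin (-0.50), and 1 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.167).

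**Figure D3:**
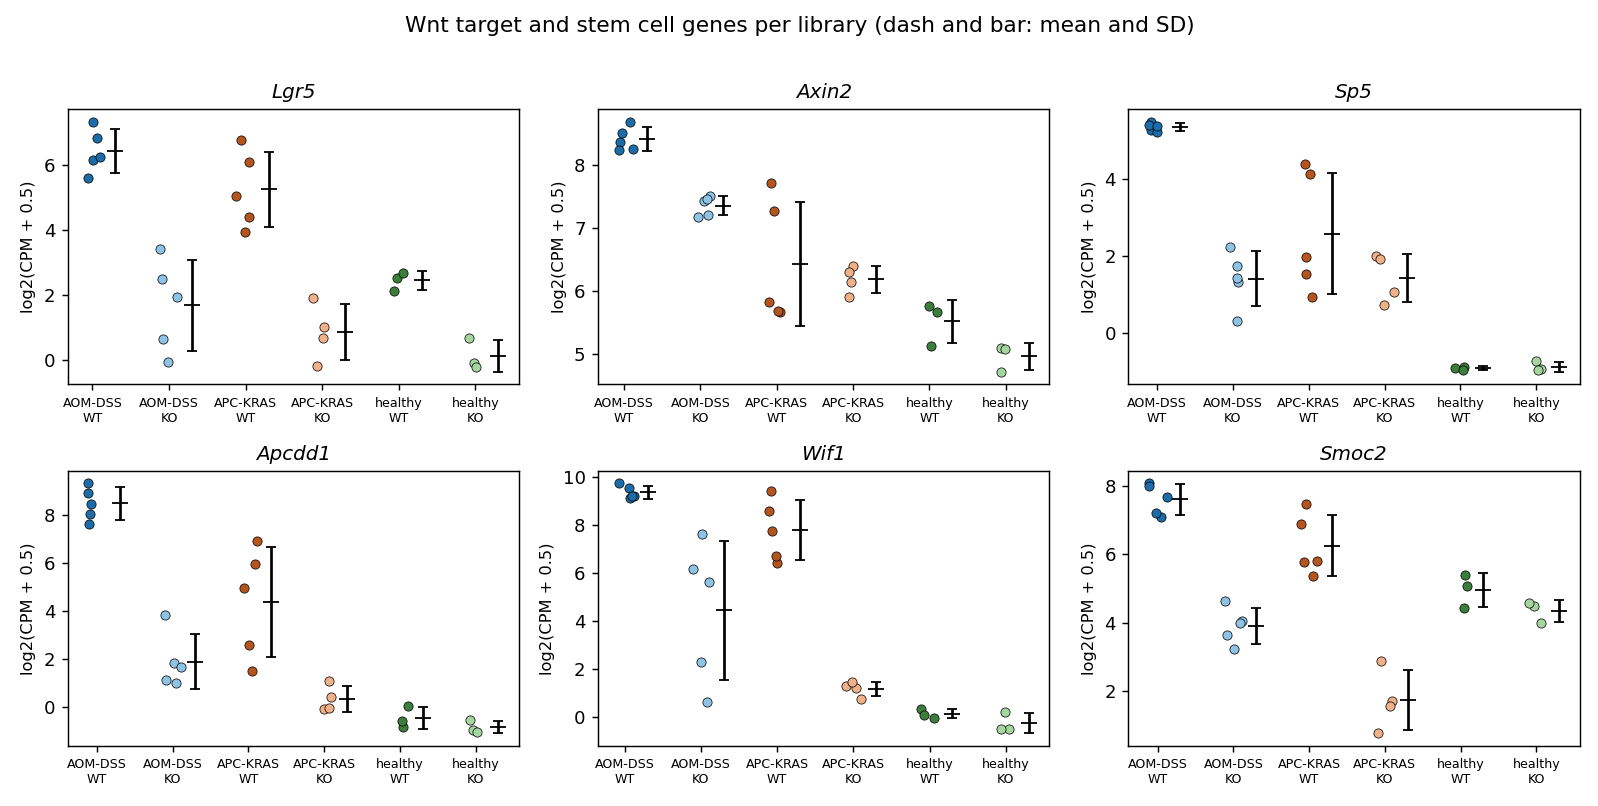
Log2(CPM + 0.5) of Lgr5, Axin2, Sp5, Apcdd1, Wif1 and Smoc2 on the y axis in each library, by group on the x axis, where points are libraries and the dash and bar are the mean and SD of 3 to 5 libraries. In AOM-DSS tumours Axin2 averages 164.7 CPM in knockout and 343.8 CPM in wild type, and Wif1 averages 1.79 CPM in APC-KRAS tumours labelled knockout against 298.5 CPM in wild type.

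In AOM-DSS tumours 17 of 24 mesenchymal genes fell and none rose (20 and 0 adjusted over the list alone, camera adjusted p = 5.88e-09, adjusted p = 0.504 with an estimated correlation). Vim, the intermediate filament of mesenchymal cells, fell by 3.04 (SE 0.40, adjusted p = 0.00124), from 514.3 ± 142 to 64.8 ± 32.5 CPM. The cadherin Cdh11 and the transcription factor Twist2 fell by 3.08 and 3.40. Markers of other cell types moved with this list. Of 16 fibroblast markers 8 fell, such as Pdgfrb (-1.72), and of 13 endothelial markers 4 fell, such as Cldn5 (-2.75), with 0 rising in either (9 and 10 fell adjusted over the list alone). Both lists were lower (camera adjusted p = 0.000591 and 0.000568, adjusted p = 0.603 and 0.603 with an estimated correlation). Uchl1 (-4.32) was the 1 of 5 neuron and glia markers that fell (1 adjusted over the list alone, camera adjusted p = 0.193). None of 12 smooth muscle markers passed (0 adjusted over the list alone, camera adjusted p = 0.812), although its median was 0.15 and camera pointed down, and that list was called lower without knockout tumour 5 (adjusted p = 0.0331, from 0.0331 to 0.991 over its alternatives). Of 5 erythroid genes 3 fell, including Alas2 (-2.16) and Hbb-bs (-1.57) (5 adjusted over the list alone, camera adjusted p = 0.00742, adjusted p = 0.603 with an estimated correlation). The erythroid call was lost with the stricter filter (adjusted p = 0.0769), in the fit of all 6 groups (0.137) and with the fibroblast and endothelial index as covariate (0.146), in a range of 0.000516 to 0.146. Those of Alas2 and Hbb-bs were lost in the last 2 of these (up to 0.241 and 0.412).

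Epithelial genes rose in AOM-DSS knockout tumours: 13 of 21 rose and none fell (15 and 0 adjusted over the list alone, camera adjusted p = 9.99e-06, adjusted p = 0.603 with an estimated correlation). The brush border protein gene Vil1 rose by 1.42 (SE 0.19, adjusted p = 0.00136) and the crypt factor Klf5 by 1.28 (SE 0.19, adjusted p = 0.00181). Of 15 cholesterol synthesis genes 12 rose and none fell (13 and 0 adjusted over the list alone, camera adjusted p = 1.81e-06, adjusted p = 0.603 with an estimated correlation). Examples were Idi1 (0.82), Acat2 (0.76) and Lss (1.34), enzymes of the pathway. Of 24 proliferation genes 6 rose, among them the replication helicase subunit Mcm6 (1.09, SE 0.16, adjusted p = 0.00196) (6 adjusted over the list alone, camera adjusted p = 0.000219, adjusted p = 0.634 with an estimated correlation), a list not called with the fibroblast and endothelial index as covariate (adjusted p = 0.0582, from 6.57e-10 to 0.0582 over its alternatives). Of 19 MAPK output genes 10 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00336, adjusted p = 0.603 with an estimated correlation), including the feedback inhibitor Spred1 (-0.58), Etv5 (-3.08) and Phlda1 (-1.40). Of 12 small intestine genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.603 with an estimated correlation). The glucose transporter Slc5a1 rose by 1.70. That list's call was lost without knockout tumour 1 (adjusted p = 0.103, from 0.0112 to 0.282 over its alternatives). Of 20 colonocyte genes 4 rose, such as Ceacam1 (1.69) (3 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.646 with an estimated correlation). Its call was lost without knockout tumour 3 (adjusted p = 0.0535) or knockout tumour 5 (adjusted p = 0.0591), and it ran from 0.000686 to 0.838 over its alternatives.

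Among immune genes of AOM-DSS tumours, 7 of 10 MHC class II genes rose and none fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.9e-08, adjusted p = 0.504 with an estimated correlation). H2-DMa rose by 1.63, the invariant chain gene Cd74 by 1.14 (SE 0.15, adjusted p = 0.00136) and the master regulator Ciita by 2.35. Of 21 interferon response genes 6 rose and 1 fell, with Gbp2 (1.57) and Oasl2 (1.17) among the rises (7 and 1 adjusted over the list alone, camera adjusted p = 0.00103, adjusted p = 0.646 with an estimated correlation). Of 17 cytokine and inflammation genes 7 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.000885, adjusted p = 0.603 with an estimated correlation). The prostaglandin synthase Ptgs2 fell by 3.15 and Il6 by 3.06, whereas Nos2 rose by 1.70. Of 13 neutrophil markers 3 fell (4 adjusted over the list alone, camera adjusted p = 0.00225, adjusted p = 0.603 with an estimated correlation), and the call was lost with the fibroblast and endothelial index as covariate (adjusted p = 0.293, from 0.000134 to 0.293 over its alternatives). Of 17 T and NK cell markers 6 rose, including Cd8a (2.04), and 1, Zap70 (-2.52), fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.648 with an estimated correlation). That call was lost without knockout tumour 1 (adjusted p = 0.0593) or wild-type tumour 2 (adjusted p = 0.0928), in a range of 0.000808 to 0.257. Macrophage markers, with 1 of 13 falling (0 adjusted over the list alone), were placed lower (camera adjusted p = 0.028, adjusted p = 0.648 with an estimated correlation). That call was lost without wild-type tumour 3 (adjusted p = 0.0658) or 5 (adjusted p = 0.0591), in a range of 0.00404 to 0.556.

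Other epithelial lists of AOM-DSS tumours were not called by camera. They were tuft cells (2 rose, such as Il17rb, and 2 fell of 13, adjusted p = 0.797), enteroendocrine cells (0 and 2 of 14, 0.776), Paneth and deep secretory cells (0 and 3 of 15, 0.443) and the regenerative list (2 rose, such as Ly6a, and 2 fell of 15, 0.632). Adjusted over the list alone these counts were 2 and 2, 0 and 2, 0 and 3, and 2 and 4. Notch genes (1 and 2 of 14, 0.596), TGF-beta and BMP genes (2 and 5 of 13, 0.512), distal colon genes (3 and 0 of 12, 0.66) and B and plasma cell markers (0 and 0 of 12, 0.672) were not called either. Adjusted over the list alone these were 1 and 2, 2 and 5, 2 and 0, and 0 and 0. The Notch list had a median of 0.002 and a mean of -0.049, with camera pointing up. Goblet cell genes (2 rose of 17, 1 adjusted over the list alone, 0.329) and dissociation stress genes (0 of 15, 0 adjusted over the list alone, 0.105) were called higher without wild-type tumour 2 (adjusted p = 0.0317 and 0.00705, from 0.0317 to 0.973 and from 0.00705 to 0.961 over their alternatives).

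In APC-KRAS tumours labelled knockout, camera at the preset correlation placed the Wnt target and neutrophil lists lower and the tuft cell and T and NK cell lists higher, and Hoxa13 and Hoxb13 were nearly absent. Of 16077 genes tested, 1637 passed, 544 higher and 1093 lower, among them 59 and 90 unnamed gene models. Directions are relative to libraries labelled wild type and rest on the labels, which the counts of Bcl9 and Bcl9l cannot check. Hoxa13, a patterning gene of the hindgut (chromosome 6, 52257694 to 52260880), was 0.42 ± 0.30 CPM against 72.1 ± 30.3 CPM, a fall by 7.36 (SE 0.67, adjusted p = 0.00128). Hoxb13 (chromosome 11, 96194316 to 96197447) fell by 8.35 (SE 1.15, adjusted p = 0.00349). Serpinb11 fell by 8.38, the pentraxin-like Mptx1 by 8.92, the keratin Krt17 by 7.88, the ligand gene Wnt10a by 7.85 and T (brachyury) by 8.55. The factor Osr2 rose by 7.67 (SE 0.69, adjusted p = 0.00128) and was 27.36 ± 11.96 CPM in tumours labelled knockout and 0.13 ± 0.11 CPM in wild type. Hoxb7 rose by 6.78 (SE 1.07, adjusted p = 0.00543), H2-T3, a non-classical MHC gene, by 6.59, the phospholipase Pla2g4c by 6.02, Acaa1b by 5.62, Cyp2d26 by 5.18 and Cyp2c66 by 5.04. The number of genes called was 890 without labelled-knockout tumour 5, 948 without 32_1a, 1021 without 32_1b, 847 without 32_2a and 955 without wild-type tumour 16. With the 3 libraries of the 32 series summed into 1 it was 218, of which 206 were among the 1637, and of the single genes followed through the alternatives 71 lost the call and 32 did not.

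Of 28 Wnt target genes tested in APC-KRAS tumours 11 fell and none rose (13 and 0 adjusted over the list alone, camera adjusted p = 4.56e-08, adjusted p = 0.319 with an estimated correlation). The secreted inhibitor Wif1 (chromosome 10, 121033960 to 121100650) fell by 7.38 (SE 0.80, adjusted p = 0.00164) and was 1.79 ± 0.44 CPM against 298.5 ± 252 CPM. The transcription factor Prox1 fell by 6.04, Dkk2 by 6.09 and Lgr5 by 4.96. Of 24 stem cell genes 6 fell, with Smoc2 by 4.73, and none rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.319 with an estimated correlation). Of 24 mesenchymal genes 6 fell, such as Spp1 (-5.96), Mmp14 (-2.60) and the fibronectin gene Fn1 (-3.48), and none rose (12 and 0 adjusted over the list alone, camera adjusted p = 6.39e-08, adjusted p = 0.222 with an estimated correlation). Fibroblast markers moved with them: 4 of 15 fell, such as Col1a1 (-2.75) (10 adjusted over the list alone, camera adjusted p = 1.25e-05, adjusted p = 0.319 with an estimated correlation). Of 14 regenerative and fetal-like genes 6 fell, including Msln (-7.20) and Tacstd2 (-6.44) (6 adjusted over the list alone, camera adjusted p = 0.000668, adjusted p = 0.133 with an estimated correlation). Within the BCL9-beta-catenin complex list Bcl9 rose and Lef1 (-3.89) and Pygo1 fell among 11 genes (1 and 2 adjusted over the list alone, camera adjusted p = 0.826). The Pygo1 call was lost without 32_1a (adjusted p = 0.0812), 32_1b (0.076) or 32_2a (0.0806).

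Of 12 tuft cell genes tested in APC-KRAS tumours 9 rose and none fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.49e-08, adjusted p = 0.222 with an estimated correlation). Tuft cells are chemosensory cells of the gut lining. Their kinase marker Dclk1 rose by 3.56 (SE 0.57, adjusted p = 0.00562) and the taste channel Trpm5 by 4.45, with Rgs13 and Siglec5 rising by 4.35 and 4.79. Of 13 enteroendocrine genes 5 fell, such as the hormone genes Insl5 (-5.40) and Pyy (-3.98) and the factor Isl1 (-7.00), and none rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000287, adjusted p = 0.153 with an estimated correlation). Of 17 goblet cell genes 2 rose, with the mucin Muc4 by 2.79, and 2 fell, with Spink4 by 2.28 (2 and 9 adjusted over the list alone). The goblet list was placed lower (camera adjusted p = 0.00647, adjusted p = 0.402 with an estimated correlation). Of 14 Paneth and deep secretory cell genes 4 fell, including Reg4 (-2.64) (5 adjusted over the list alone, camera adjusted p = 0.00961, adjusted p = 0.331 with an estimated correlation). Both of these calls were lost without 32_1a (adjusted p = 0.0865 and 0.0865, from 0.00019 to 0.0865 and from 0.000258 to 0.13 over their alternatives). Of 20 colonocyte genes 3 rose, such as Cdhr5 (1.48) (3 adjusted over the list alone, camera adjusted p = 0.000915), and of 21 epithelial genes 2 rose (2 adjusted over the list alone, 0.00327). These had adjusted p = 0.402 and 0.402 with an estimated correlation. None of 15 cholesterol genes passed (0 adjusted over the list alone) while the list was placed higher (camera adjusted p = 0.00327, adjusted p = 0.402 with an estimated correlation).

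Immune genes moved apart in APC-KRAS tumours. Of 16 T and NK cell markers 11 rose and none fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.58e-14, adjusted p = 0.153 with an estimated correlation). The chemokine Ccl5 rose by 3.75 (SE 0.47, adjusted p = 0.00288), from 1.70 ± 0.94 to 22.6 ± 7.99 CPM, Cd8b1 by 4.36 and Cd5 by 3.62. Of 12 neutrophil markers 9 fell and none rose (10 and 0 adjusted over the list alone, camera adjusted p = 1.5e-14, adjusted p = 0.133 with an estimated correlation). The alarmin S100a9 fell by 6.07 (SE 0.58, adjusted p = 0.00128), from 59.1 ± 31.6 to 0.86 ± 0.37 CPM, Retnlg by 6.75 and the receptor Cxcr2 by 5.82. Of 16 cytokine and inflammation genes 11 fell, such as Cxcl1 (-3.83), Cxcl2 (-4.01) and Ptgs2 (-4.89), and none rose (12 and 1 adjusted over the list alone, camera adjusted p = 3.65e-12, adjusted p = 0.133 with an estimated correlation). Of 9 MHC class II genes 5 rose, such as H2-DMa (2.48) and Cd74 (2.21) (8 adjusted over the list alone, camera adjusted p = 4.52e-09, adjusted p = 0.153 with an estimated correlation). Of 21 interferon response genes 5 rose, such as Oas1a (1.38) (5 adjusted over the list alone, camera adjusted p = 1.8e-08, adjusted p = 0.319 with an estimated correlation). None of 14 macrophage and none of 8 B and plasma cell markers passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.486 and 0.308).

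The remaining APC-KRAS lists held few called genes. Of 19 MAPK output genes 2 fell, with Etv5 by 3.70 (3 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.319 with an estimated correlation). That call was lost without wild-type tumour 15 (adjusted p = 0.0611, from 0.00191 to 0.0611 over its alternatives). Of 3 neuron and glia markers 2 fell, with the receptor Ret by 3.35 (2 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.222 with an estimated correlation). The neuron and glia call was lost in the fit of all 6 groups (adjusted p = 0.0682, from 0.00905 to 0.0682 over its alternatives). None of 12 endothelial markers passed (0 adjusted over the list alone), and the list was placed lower (camera adjusted p = 0.0223, adjusted p = 0.596 with an estimated correlation). That call was lost without 32_2a (adjusted p = 0.14) or wild-type tumour 16 (adjusted p = 0.119), in a range of 0.00399 to 0.14. Proliferation genes (1 rose of 24, 0.44) and TGF-beta and BMP genes (1, Bambi, fell of 13, 0.119) were called without 32_1a (adjusted p = 0.0132 and 0.0309, from 0.0132 to 0.768 and from 0.0309 to 0.301 over their alternatives). Not called were the lists for Notch (1 rose, Dtx1, and 2 fell of 14, 0.452), small intestine (0 and 1 of 11, 0.478), distal colon (0 and 2 of 11, Hoxa13 and Hoxb13, 0.486), smooth muscle (1, Mylk, and 0 of 12, 0.723), dissociation stress (1 and 0 of 15, 0.539) and erythroid genes (0 and 0 of 5, 0.301). Adjusted over the list alone, the counts that rose and fell were 1 and 2, 0 and 1, 2 and 2, 1 and 0, 1 and 0, and 0 and 0 for these 6, 1 and 0 for proliferation and 0 and 1 for TGF-beta and BMP. The small intestine list had a median of -0.08 while camera pointed up.

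**Figure D4:**
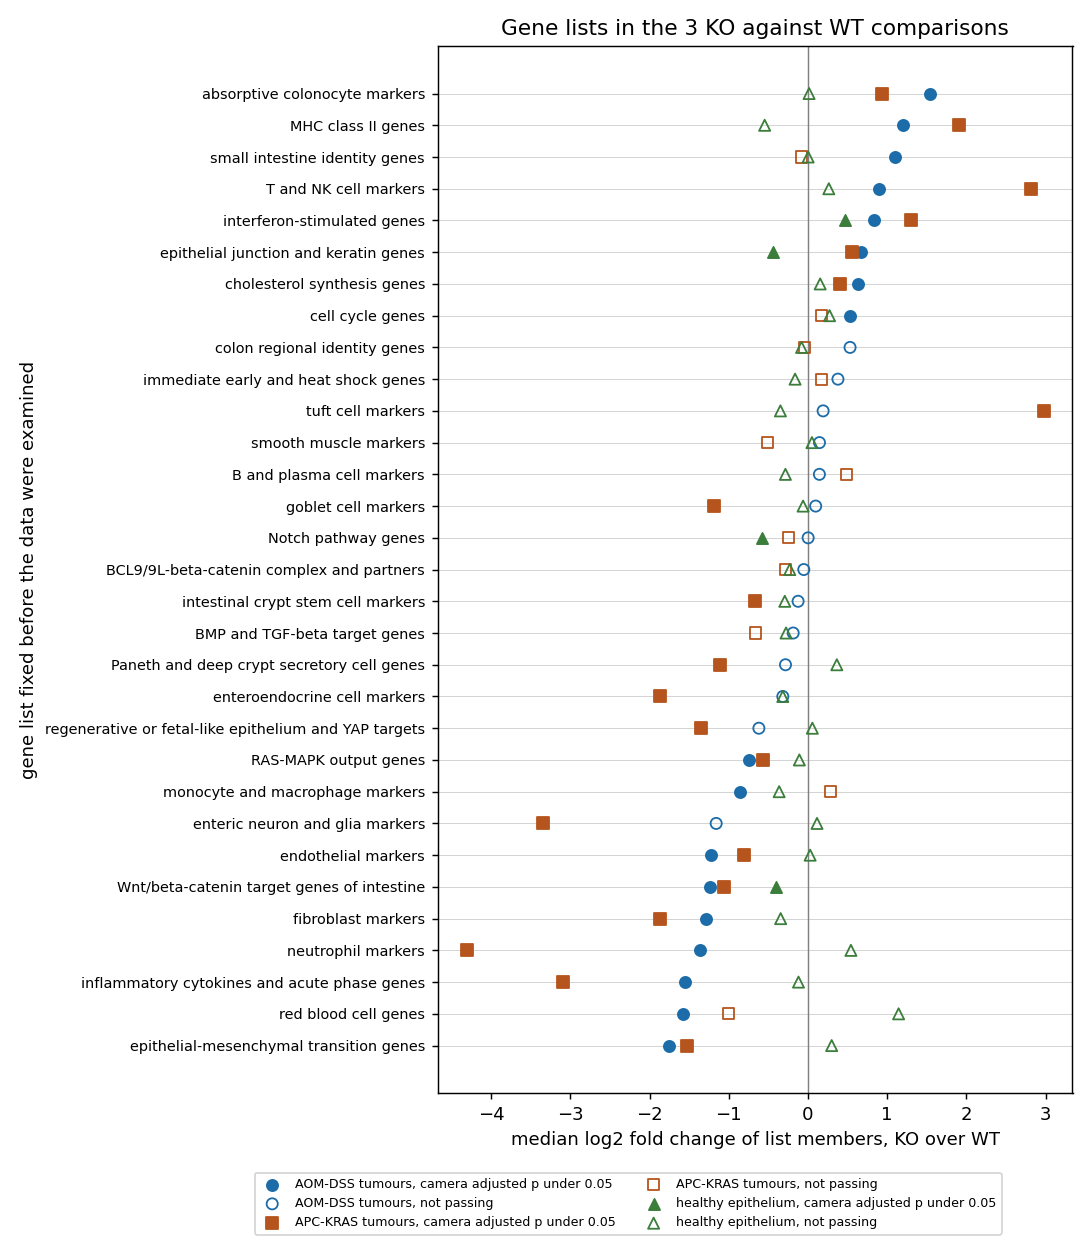
Median log2 fold change, knockout minus wild type, of the members of each gene list on the x axis, for the 3 knockout comparisons, with filled points where the camera adjusted p was under 0.05. The neutrophil list has a median of -4.31 and the tuft cell list a median of 2.98 in APC-KRAS tumours labelled knockout, and the mesenchymal list a median of -1.76 in AOM-DSS tumours.

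In healthy colon epithelium few genes passed, and the Wnt target and epithelial lists were lower in knockout. By edgeR 3 of 16870 genes passed, all higher and none lower, with 3242 genes at an unadjusted p under 0.05. DESeq2 called 1636 genes and limma-voom 294. The genes were the pseudogenes Gm9825 (log2 change 6.57, adjusted p = 0.00675) and Gm14292 (7.38, adjusted p = 0.0174), named because only 3 passed, and the lipid hydrolase gene Abhd3 (chromosome 18, 10642092 to 10706771). Abhd3 was 22.3 ± 3.92 CPM in knockout and 4.22 ± 0.46 CPM in wild type (SD, n = 3 and 3), a log2 change of 2.39 (SE 0.20, adjusted p = 0.0174). Its call was lost without knockout library 5 (adjusted p = 0.157), 6 (0.0524) or 7 (0.0567) or wild-type library 1 (0.133) or 2 (0.227), and the p ranged from 2.72e-27 to 0.227. The number of genes called was 0 without knockout library 5, 1 without knockout library 6, 1 without wild-type library 1, 0 without wild-type library 2 and 402 without wild-type library 3. Wild-type library 3 was the only healthy library with Xist above Ddx3y (4244 against 15 counts) and had the highest total, 105860869 counts. Its omission thus also removed the sex difference within healthy epithelium, and why more genes then passed was not tested.

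Of 24 Wnt target genes tested in healthy epithelium none passed over all genes, and 7 lower and 1 higher did so adjusted over the list alone (camera adjusted p = 0.00371, adjusted p = 0.878 with an estimated correlation). Lgr5 was 0.64 ± 0.41 CPM in knockout and 5.00 ± 1.04 CPM in wild type (log2 change -3.01, SE 0.46, adjusted p = 0.0908), and the stem cell factor Ascl2 had a log2 change of -1.82 (SE 0.30, adjusted p = 0.0908). The 3 knockout and 3 wild-type libraries did not overlap for either gene, which chance gives for 10% of unchanged genes. DESeq2 placed both past the threshold (adjusted p = 2.44e-08 and 1.68e-05, against highest values of 0.759 and 0.759 over their alternatives). Of 21 epithelial genes 10 were lower adjusted over the list alone, such as the junction gene Pkp3 (-1.06) and the factor Elf3 (-0.81) (camera adjusted p = 7.64e-05, adjusted p = 0.878 with an estimated correlation). Of 13 Notch genes 3 were lower adjusted over the list alone, including the ligand gene Jag2 (-2.67) and the modifier Lfng (-1.13) (camera adjusted p = 0.00399, adjusted p = 0.878 with an estimated correlation). The Notch call was lost with the stricter filter, which kept 8 of these genes (adjusted p = 0.101, from 0.000506 to 0.101 over its alternatives). With wild-type library 3 left out Ascl2 (adjusted p = 0.044), Pkp3 (0.0428), Elf3 (0.05) and Jag2 (0.0428) passed, each with a highest value of 0.759 over its alternatives. The interferon list was placed higher with no member called (0 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.932 with an estimated correlation). That call was lost without knockout library 6 (adjusted p = 0.2) or 7 (0.0508) or wild-type library 2 (0.284) or 3 (0.122), in a range of 1.12e-08 to 0.284.

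No member of the other 28 lists passed over all genes in healthy epithelium. Adjusted over the list alone, 5 of 23 stem cell genes, 1 of 10 complex genes (Bcl9l), 1 of 17 goblet genes (Tff3, log2 change -0.67), 2 of 11 TGF-beta and BMP genes (Id3, -1.27, and Id1, -0.69) and 2 of 15 dissociation stress genes (Ier2, -1.72, and Junb, -3.04) were lower. Of 18 enteroendocrine genes 1, the somatostatin gene Sst (-3.87), was lower and 1 higher. Camera gave adjusted p = 0.1, 0.364, 0.839, 0.205, 0.164 and 0.489 for these lists. It gave 0.219 for mesenchymal, 0.486 for colonocyte, 0.499 for tuft, 0.0768 for Paneth, 0.0628 for proliferation, 0.757 for regenerative, 0.83 for MAPK, 0.219 for cholesterol, 0.646 for small intestine and 0.99 for distal colon genes. It gave 0.499 for fibroblast, 0.83 for smooth muscle, 0.939 for endothelial, 0.948 for neuron and glia, 0.219 for T and NK cell, 0.899 for B and plasma cell, 0.234 for macrophage, 0.164 for neutrophil, 0.939 for cytokine, 0.108 for MHC class II, 0.372 for erythroid and 0.0768 for sex-linked genes. Camera's direction differed from that of the median or the mean for smooth muscle (median 0.05, mean -0.01, camera up), endothelial (median 0.03, camera down), neuron and glia (mean -0.07, camera up) and B and plasma cell genes (median -0.29, camera up). Without wild-type library 3, Id3, Id1, Ier2, Junb and Sst passed (adjusted p = 0.0428 for each, with highest values of 0.759 over their alternatives). With single libraries left out, 15 of these 28 lists were called. They were, by library left out, MHC class II (0.0424) and T and NK cell genes (0.018) without knockout library 5, and stem (0.0172), tuft (0.00114), Paneth (0.0061), proliferation (0.00194), fibroblast (0.000452), neutrophil (0.00135) and dissociation stress genes (0.00391) without knockout library 6. Without knockout library 7 they were Paneth (0.0122), proliferation (0.0122), cholesterol (0.03), MHC class II (0.00138) and erythroid genes (0.0369). Without wild-type library 1 they were mesenchymal (0.0162), Paneth (0.00287), cholesterol (0.045), T and NK cell (0.0162), macrophage (0.041), MHC class II (0.00472) and sex-linked genes (0.0157). Without wild-type library 2 they were Paneth (0.0276), neutrophil (0.00553), MHC class II (0.0343), dissociation stress (0.0343) and sex-linked genes (0.00553), and without wild-type library 3 stem (0.0351), tuft (0.0312), proliferation (0.000215), B and plasma cell (0.00631), dissociation stress (0.0139) and sex-linked genes (0.0064).

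The differences between knockout effects were tested as interactions. Between AOM-DSS tumours and healthy epithelium 639 of 18396 genes differed, 263 with a more positive and 376 with a more negative effect in tumours. Myc (2.20, SE 0.37, adjusted p = 0.00636), Klf5 (1.78), the Myc-regulated gene Cdca7 (1.75) and Btnl2 (4.06) were more positive, and Svopl (-7.99) and Gabra4 (-7.88) more negative. Among the lists, 3 of 21 epithelial genes (12 adjusted over the list alone, camera adjusted p = 3.41e-07, adjusted p = 0.392 with an estimated correlation) and 3 of 10 MHC class II genes (7 adjusted over the list alone, 2.56e-06, adjusted p = 0.392 with an estimated correlation) were more positive. Of 24 mesenchymal genes 2 were more negative (3 adjusted over the list alone, camera adjusted p = 6e-07, adjusted p = 0.392 with an estimated correlation). Wnt targets were not called (1 and 1 of 29, 5 and 9 adjusted over the list alone, camera adjusted p = 0.0971), except without AOM-DSS knockout tumour 1 (adjusted p = 0.0496, from 0.0496 to 0.592 over its alternatives). This count ranged from 129 without healthy wild-type library 2 to 1363 without APC-KRAS wild-type tumour 17. It was 358 and 346 without AOM-DSS knockout tumours 3 and 5, 411 and 370 without wild-type tumours 3 and 4, 225, 149 and 337 without healthy knockout libraries 5, 6 and 7, and 290 and 250 without healthy wild-type libraries 1 and 3. With RLE scaling 198 were more positive and 451 more negative, and with upper-quartile scaling 203 and 476.

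Between APC-KRAS tumours labelled knockout and healthy epithelium 1126 of 18396 genes differed, 425 more positive and 701 more negative in tumours. Bcl9 (1.83, SE 0.26, adjusted p = 0.00171) and Osr2 (7.93) were more positive. Hoxa13 (-7.33, SE 1.02, adjusted p = 0.0016), Hoxb13 (-7.18), Mptx1 (-9.36), Tex15 (-9.03), Prox1 (-5.29) and Smoc2 (-4.07) were more negative. More positive were 6 of 17 T and NK cell markers, with Cd8b1 at 4.29 (11 adjusted over the list alone, camera adjusted p = 4.92e-10, adjusted p = 0.281 with an estimated correlation). So were 6 of 14 tuft cell genes, with Siglec5 at 4.53 (11 adjusted over the list alone, 6.7e-07, adjusted p = 0.281 with an estimated correlation) and 7 of 10 MHC class II genes, with Cd74 at 2.81 (9 adjusted over the list alone, 9.24e-11, adjusted p = 0.247 with an estimated correlation). Of 13 neutrophil markers 6 were more negative, with S100a9 at -6.73 (10 adjusted over the list alone, camera adjusted p = 1.5e-08, adjusted p = 0.281 with an estimated correlation). Counts of genes were 401, 400 and 568 without healthy knockout libraries 5, 6 and 7, 401, 365 and 723 without healthy wild-type libraries 1, 2 and 3, 537 without 32_1a, 702 without APC-KRAS wild-type tumour 16 and 4199 without wild-type tumour 17. With the 32 series summed, 21 of the 58 genes followed through the alternatives lost the call.

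Between the 2 tumour models 841 of 18396 genes differed in their knockout effect, 636 more positive and 205 more negative in AOM-DSS tumours. Hoxa13 (8.04, SE 0.92, adjusted p = 5.72e-05) and Mptx1 (10.71) were more positive, as were Slc12a2 (2.06) and Klf5 (1.38). Hoxb7 (-11.22, SE 1.13, adjusted p = 2.33e-05), its neighbour Hoxb3os (-9.02), Osr2 (-8.27) and Bcl9 (-1.002, SE 0.23, adjusted p = 0.0153) were more negative. The effect on T and NK cell markers was more negative in AOM-DSS tumours for 3 of 17, with Lck at -2.03 (8 adjusted over the list alone, camera adjusted p = 1.68e-11, adjusted p = 0.5 with an estimated correlation). It was more negative for 3 of 14 tuft cell genes, with Hck at -3.65 (9 adjusted over the list alone, 1.85e-08, adjusted p = 0.5 with an estimated correlation), and more positive for 4 of 17 goblet cell genes, with Spink4 at 2.44 (7 and 1 lower adjusted over the list alone, 6.77e-05, adjusted p = 0.539 with an estimated correlation). The mesenchymal list was not called (0 of 24, 0 adjusted over the list alone, camera adjusted p = 0.623), with a median of -0.01, a mean of 0.04 and camera pointing down. The count was 359 and 414 without AOM-DSS knockout tumours 2 and 4, 406, 424, 329 and 395 without wild-type tumours 1, 3, 4 and 5, 427 without labelled-knockout tumour 5, and 489 and 1301 without APC-KRAS wild-type tumours 13 and 17. With RLE scaling 358 were more positive and 236 more negative, and with DESeq2 762 and 555. Of the 48 genes followed through the alternatives 28 lost the call with the 32 series summed, 19 with limma-voom and 9 with RLE scaling.

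Wild-type tumours were set against wild-type healthy epithelium as context. Tumours were whole macrodissected tissue and the healthy samples were EDTA-released epithelium, so handling and cell content differed together with the tissue. In AOM-DSS tumours 9347 of 18396 genes differed, 4719 higher and 4628 lower. Of 29 Wnt targets 24 were higher and 1 lower, with Sp5 at 10.27 and Axin2 at 2.89 (24 and 1 adjusted over the list alone, camera adjusted p = 1.09e-09, adjusted p = 0.168 with an estimated correlation). All 13 endothelial markers, with Cdh5 at 7.48, and 15 of 16 fibroblast markers, with Col1a1 at 7.19, were higher (13 and 15 adjusted over the list alone, camera adjusted p = 1.09e-09 and 4.9e-08, adjusted p = 0.168 and 0.168 with an estimated correlation). All 17 goblet cell genes, with the secretory lineage factor Atoh1 at -3.56, and 17 of 20 colonocyte genes, with the chloride exchanger Slc26a3 at -8.64, were lower (17 and 17 adjusted over the list alone, camera adjusted p = 4.9e-08 and 1.17e-07, adjusted p = 0.168 and 0.181 with an estimated correlation). With a stromal and immune index as covariate 4107 genes differed.

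In APC-KRAS tumours 8307 of 18396 genes differed from healthy epithelium, 4616 higher and 3691 lower. The metalloproteinase genes Mmp10 (15.70) and Mmp13 (11.85), T (12.39) and Serpinb11 (12.52) were among the largest rises. Of 29 Wnt targets 23 were higher and 1 lower, with the Wnt inhibitor Notum at 9.07 (26 and 1 adjusted over the list alone, camera adjusted p = 1.38e-07, adjusted p = 0.257 with an estimated correlation). Of 15 regenerative and fetal-like genes 12 were higher, with Ctgf at 10.75 (12 adjusted over the list alone, camera adjusted p = 5.68e-07), and this call held with an estimated correlation (adjusted p = 0.0337). Of 17 goblet cell genes 12 were lower, with Fcgbp at -4.54 (14 adjusted over the list alone, camera adjusted p = 7.14e-07, adjusted p = 0.257 with an estimated correlation), and 7 of 10 MHC class II genes were lower, with Cd74 at -2.21 (7 adjusted over the list alone, 0.000746, adjusted p = 0.339 with an estimated correlation). The Y-linked gene Uba1y was lower by the sex composition given above, with a log2 change of -11.01.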

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

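Of the tests below, the rank test of the Hox genes, the comparison of Hoxa13 and Hoxb13 between tumour models and the test of T and NK cell against fibroblast genes were chosen only after the result was seen, as were the fibroblast and endothelial covariate, the omission of AOM-DSS knockout tumours 3 and 5, the test of exchanged labels and both tests of genes of healthy epithelium, of which the size of the rise was chosen after the rise itself was seen, as was the comparison of epithelial lists.

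Hoxa13 and Hoxb13, which mark the hindgut, were nearly absent from APC-KRAS tumours labelled knockout. That direction was drawn from labels that the Bcl9 counts cannot check. A general effect of losing Bcl9 and Bcl9l is argued against by the difference of the knockout effect between AOM-DSS and APC-KRAS tumours, 8.045 for Hoxa13 (adjusted p = 5.72e-05) and 8.363 for Hoxb13 (adjusted p = 0.00158, lost with limma-voom at 0.0545). Over 19 Hox genes, higher paralog numbers went with more negative changes (Spearman rho across genes -0.632, one-sided permutation p = 0.00231). These 19 include Hoxa13 and Hoxb13, which prompted the test, and the permutation treats genes of a cluster as independent. The rank test is therefore no separate evidence for position. Tumours from different positions along the gut could give such a trend. The small intestine list was not called (camera adjusted p = 0.478), but it cannot speak to positions within the large bowel. With the regional index as covariate, 99 of the genes followed through the alternatives kept their direction and side of the threshold, and 4 lost the call. That index is built from the small intestine and distal colon lists, Hoxa13 and Hoxb13 among them, and cannot settle position. Position cannot be told apart from other causes. With 32_1a, 32_1b and 32_2a summed to 1 sample Hoxa13 changed by -7.644 (adjusted p = 0.0273, from 8.11e-37 to 0.0273 over its alternatives) and Hoxb13 by -8.645 (adjusted p = 0.0565, from 2.34e-19 to 0.0565). The Hoxb13 change did not shrink and the summed group held fewer samples, so the lost call cannot show whether a shared animal played a part. An exchange of all labels is argued against, if both models respond alike. Of the genes called in both, 97.3% went the same way (lower 95% exact binomial bound 95.8). That bound takes genes as independent, which they are not. A single wrong label and an effect of genotype in this model alone were not tested.

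The mesenchymal list was lower in AOM-DSS knockout tumours, with a median log2 change of -1.76. An equal fall of all non-epithelial cells is argued against by the T and NK cell list. Its median lay 2.194 above that of the fibroblast list (two-sided permutation p over genes = 8e-05, although genes are not independent). The higher call of that list was lost without knockout tumour 1 (camera adjusted p = 0.0593) or wild-type tumour 2 (0.0928). Fibroblast, endothelial, macrophage, neutrophil and erythroid lists were lower, while smooth muscle, neuron and glia, and B and plasma cell lists were not called. A smaller share of several non-epithelial cell types thus stays open. An origin in knockout tumours 3 and 5 is argued against, since without them the mesenchymal list median was -1.328 (camera adjusted p = 2.29e-11). With an index of fibroblast and endothelial genes as covariate the median was -0.607. The list was still called at the preset correlation (camera adjusted p = 9.75e-06). The indexed genes were themselves lower in knockout, and the covariate cut the genes called in these tumours from 4833 to 633. The smaller median therefore cannot single out fewer fibroblasts and endothelial cells as the cause, which stays open. An index may remove the effect of such cells only in part, so whether a fall beyond theirs remains is open. Whether tumour cells themselves expressed less Vim or Twist2 stays open.

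Of the Wnt targets 17 of 29 fell and 4 rose in AOM-DSS tumours (median over all -1.24, over those called lower -3.38, camera adjusted p = 6.89e-06, adjusted p = 0.603 with an estimated correlation), and 11 of 28 fell and 0 rose in APC-KRAS tumours labelled knockout (medians -1.05 and -5.102, camera adjusted p = 4.56e-08, adjusted p = 0.319 with an estimated correlation). More normal epithelium could lower them. The 200 genes highest in the other model's wild-type tumours over healthy epithelium had medians of -1.737 (95% interval -1.944 to -1.521, 52% called lower) and -3.035 (-3.576 to -2.56, 53%). These lay past the bounds of -1.69 and -2.551 (0.5 times the fall) set before the result was seen, although the first interval includes its bound. Tumours were whole tissue and healthy samples epithelium, so these 200 genes may include genes of non-epithelial cells. A smaller share of such cells could also lower these genes and raise those of epithelium. The fall of the 200 genes therefore cannot single out normal epithelium. The 200 genes lowest in the other model's wild-type tumours rose too, by medians of 0.751 (lower 95% bound 0.608) and 0.752 (0.554). The bound first chosen was a rise above 0. For 0.5 times the fall, a share of 69% and 82.9% of epithelium with the healthy profile would raise them by 3.043 and 2.239. Their upper 95% bounds of 0.913 and 0.96 argue against that source, over these genes. All 95% intervals and bounds of this paragraph resample genes, which are not independent. They do not measure the spread between tumours. Epithelial lists that are lower in wild-type tumours moved apart: medians in AOM-DSS and APC-KRAS tumours were 1.54 and 0.93 for colonocyte genes (95% intervals 1.181 to 1.68 and 0.373 to 1.545, against 2.994 and 1.289 needed), 0.67 and 0.56 for epithelial genes (0.508 and 0.695 needed), 0.10 and -1.19 for goblet genes (2.237 and 1.827) and -0.32 and -1.87 for enteroendocrine genes (1.36 and 1.804). In AOM-DSS tumours the mean log2 CPM of colonocyte genes was 6.818 and 7.07 in knockout tumours 3 and 5. In knockout tumours 1, 2 and 4 it was 4.341 to 5.207, within wild type (4.137 to 5.578). Wnt targets were lower in every knockout tumour, at 3.83 to 5.316 against 6.216 to 6.532 in wild type. A smaller share, epithelium with another profile (such as colonocytes without secretory cells) and a loss of Wnt output through BCL9 and BCL9L in tumour cells stay open. For APC-KRAS tumours a difference of position along the gut, raised above, stays open too.

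Other splits of the libraries were counted for every comparison. Of 100 splits of the AOM-DSS libraries only the real one (1) gave 4833 genes, and the highest other gave 3. Chance can be excluded if each tumour came from a separate animal, which the labels do not say. The same holds for APC-KRAS tumours, where 1 of 100 splits, the real one, gave 1637 and the highest other 519. All splits of APC-KRAS knockout effects, the differences below included, treat 32_1a, 32_1b and 32_2a as separate samples. Chance is excluded for the APC-KRAS effect only if they are, and summed they left 218 genes. In healthy epithelium 10 splits are too few for a share under 0.05, with 3 genes for the real split and 1 for the highest other. For the differences between knockout effects, libraries were exchanged within every tissue. These splits test whether any knockout effect is present, and therefore cannot exclude chance for a difference of effects. For AOM-DSS tumours minus healthy epithelium 1 of 100 splits, the real one, gave as many genes (639 against at most 4). For APC-KRAS tumours minus healthy epithelium 2 of 100 gave as many. They were the real one, with 1126 genes (568 with these 3 libraries summed), and 1 other split with 2959. This other split exchanged labelled-knockout tumours 5 and 32_2a with wild-type tumours 16 and 17. It also moved 4 AOM-DSS libraries and left healthy epithelium in place. Why it gave more genes was not tested. For AOM-DSS minus APC-KRAS tumours 3 of 100 gave as many. The real split gave 841 (361 with these 3 libraries summed), the highest other 1430 and the next 929. The highest exchanged 8 of the 9 APC-KRAS libraries and is near the mirror of the real split for this model. For wild-type tumours against healthy epithelium 1 of 56 splits, the real one, gave as many genes in either model. Chance can be excluded if these samples too came from separate animals. The values were 9347 against 2065 for AOM-DSS and 8307 against 6293 for APC-KRAS tumours.

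Among 140 groups of 4 or 5 values, 3 held a library far from the others, fewer than the 5% that chance gives. The mean log2 CPM of the proliferation list was 5.322 in AOM-DSS knockout tumour 2 against 6.22 to 6.45 in the other 4. That of MHC class II genes was 6.804 in AOM-DSS knockout tumour 5 against 6.36 to 6.46, and that of dissociation stress genes 5.412 in AOM-DSS wild-type tumour 2 against 4.38 to 4.64.

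The genes below differed in their knockout effect between tissues by the interaction test. The effect was more positive in AOM-DSS tumours than in healthy epithelium for Xist (11.107), Btnl1 (4.753), Cldn15 (4.148), Btnl2 (4.057) and the inflammasome gene Nlrp6 (3.82), and more negative for Svopl (-7.985), Gabra4 (-7.875), Dsc3 (-7.734), the kinase gene Pdk4 (-7.19) and the lipase gene Pnliprp2 (-7.175). In APC-KRAS tumours against healthy epithelium it was more positive for Xist (10.831), Bcl9 (1.833), Osr2 (7.927), Hoxb7 (6.176), Hoxb3os (6.106) and Acaa1b (5.551). It was more negative for Six4 (-10.558), Mptx1 (-9.362), Tex15 (-9.032), Mptx2 (-8.714) and the defensin Defb45 (-8.498). The Xist values follow the sex of the mice and were -1.43 and -1.71 without healthy wild-type library 3. Between AOM-DSS and APC-KRAS tumours the effect was more positive for Mptx1 (10.707), Chodl (9.784), Hoxb13 (8.363), Hoxa13 (8.045) and the channel gene Otop2 (7.763). It was more negative for Bcl9 (-1.002), Hoxb7 (-11.22), Hoxb3os (-9.016), Osr2 (-8.273), the retinoic acid synthesis gene Aldh1a2 (-6.381) and Pdk4 (-6.247). With each of the 25 libraries left out in turn, the call was lost in 16 omissions for Acaa1b, 15 for Cldn15, 13 for Pnliprp2, 12 for Defb45, 11 for Btnl1 and Aldh1a2, 8 for Six4, Otop2 and, against healthy epithelium, Hoxb7, and 5 for Dsc3. Against healthy epithelium it was lost for Xist without healthy knockout library 5, 6 or 7 or wild-type library 3, for Pdk4 without AOM-DSS knockout tumour 5, healthy knockout library 6 or wild-type library 2 or 3, for Nlrp6 without healthy knockout library 5 or 6 or wild-type library 3, and for Hoxb3os without healthy knockout library 5 or wild-type library 1. The other calls of this paragraph held in every omission. With 32_1a, 32_1b and 32_2a summed, the calls of Acaa1b, Six4 and Defb45 against healthy epithelium and of Chodl, Otop2, Aldh1a2 and Pdk4 between tumour models were lost. With limma-voom those of Xist, Hoxb7, Hoxb3os and Defb45 against healthy epithelium and of Chodl, Hoxb13, Otop2 and Aldh1a2 between tumour models were lost. With no filter those of Btnl1, Cldn15, Pnliprp2, Hoxb7, Acaa1b, Six4 and Defb45 against healthy epithelium and of Aldh1a2 were lost, the last also with the stromal and immune covariate.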

How the results depend on the processing

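The omission of mitochondrial genes, of AOM-DSS knockout tumours 3 and 5, and of APC-KRAS wild type 17 with 32_1a, and the fibroblast and endothelial covariate, were chosen only after the results were seen. Where a count or direction moved below, the cause was not tested, apart from the smaller number of samples in fits that left out or summed libraries.

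For the knockout effect in AOM-DSS tumours the count of 4833 genes was 2782 without knockout tumours 3 and 5 and 633 with the fibroblast and endothelial covariate. With a replicate block it was 3164. Same-numbered AOM-DSS libraries had correlations of 0.037, -0.121, -0.246, -0.021 and 0.2, and only number 5 was closest to its own number. No pairing by number was seen, although 5 pairs cannot exclude one.

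In APC-KRAS tumours 1637 genes became 3062 with DESeq2, 2565 with limma-voom, 4187 in the fit of all 6 groups, 1051 with 32_1a and 32_1b summed, and 218 with all 3 libraries of the 32 series summed. In healthy epithelium the 3 genes called by edgeR (3242 at an unadjusted p under 0.05) became 14 with no filter, 1636 with DESeq2 (269 higher and 1367 lower), 294 with limma-voom, 0 with the stromal and immune covariate and 7 in the fit of all 6 groups.

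The difference between AOM-DSS tumours and healthy epithelium, 639, became 414 with no filter, 1635 with DESeq2 and 4796 with limma-voom. That between APC-KRAS tumours and healthy epithelium, 1126, became 2651 with DESeq2, 4229 with limma-voom, 2984 with the stromal and immune covariate and 568 with the 32 series summed. That between tumour models, 841, became 541 with the stricter filter, 1317 with DESeq2 and 361 with the 32 series summed. AOM-DSS wild-type tumours against healthy epithelium, 9347, became 4107 with the stromal and immune covariate.

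With each library left out the counts ranged from 3135 to 5251 in AOM-DSS tumours, 847 to 1920 in APC-KRAS tumours and 0 to 402 in healthy epithelium. For the differences they ranged from 129 to 1363 (AOM-DSS minus healthy), 365 to 4199 (APC-KRAS minus healthy) and 329 to 1301 (AOM-DSS minus APC-KRAS). Wild-type tumours against healthy epithelium gave 8006 to 9919 and 6242 to 9523.

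Upper-quartile factors shifted the median log2 change of all genes by -0.166 (AOM-DSS minus healthy), -0.108 (APC-KRAS minus healthy), 0.167 and 0.129 (AOM-DSS and APC-KRAS wild-type tumours against healthy). RLE factors and DESeq2 shifted it by -0.12 and -0.119 for AOM-DSS minus APC-KRAS.

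Directions reversed in few results, where a list's direction is that of camera. With the fibroblast and endothelial covariate it turned to higher for the fibroblast (median 0.064), smooth muscle (1.808) and macrophage (0.229) lists in AOM-DSS tumours. The smooth muscle median was above 0 without the covariate too (0.145). Bcl9l in APC-KRAS tumours was 0.74 with limma-voom and 0.205 without wild type 17 and 32_1a, and ranged from -0.952 to 0.861 with single libraries left out. The difference of Bcl9l between tumour models was 0.025 with 32_1a and 32_1b summed and ranged from -1.459 to 0.388. The difference of Xist ranged from -1.431 to 13.367 (AOM-DSS minus healthy) and from -1.708 to 13.089 (APC-KRAS minus healthy). With the stromal and immune covariate, AOM-DSS wild-type tumours against healthy epithelium gave -0.679 for Derl3, -0.966 for Tnfrsf17, and medians of -1.812 for the T and NK cell list (-0.168 without the covariate) and -2.923 for the B and plasma cell list. APC-KRAS tumours gave a median of -2.336 for the last.

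Apart from single omissions, 6115 gene results kept their direction and side of the threshold, 566 lost the call, 43 gained it and 5 reversed, as against 2571, 82, 49 and 6 for lists, where a list uncalled in both fits counts as kept. With single omissions the numbers were 10663, 1033, 19 and 4 for genes and 4560, 107, 110 and 0 for lists. At the depths and group sizes here, simulated 2-fold changes were recovered for 43.67%, 3.33% and 32.33% of genes in AOM-DSS tumours, APC-KRAS tumours and healthy epithelium, so most simulated changes of that size were missed.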

Other observations

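No test below was fixed before the data were examined, and the genes named were chosen after their values were seen.

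Both tumour models, which share no library, moved many of the same genes in the same direction. Of 15879 genes tested in both, 241 were higher and 476 lower in both (75.9 and 147.1 for independent lists), and 9 and 11 went opposite ways (160 and 69.8 for independent lists). Directions in APC-KRAS tumours rest on the labels, which the Bcl9 counts cannot check. An exchange of these labels would have reversed the shared direction. The transporter-like Svopl had log2 changes of -7.26 in AOM-DSS and -6.41 in APC-KRAS tumours, while Btnl2 rose by 4.07 and 2.86, the mucin Muc4 by 2.52 and 2.79 and the aldehyde dehydrogenase Aldh1b1 by 2.61 and 2.52. Across genes, which are not independent replicates, the changes of both models had a Pearson correlation of 0.568 and a Spearman correlation of 0.521. Over 15305 genes tested in all 3 tissues the Pearson correlation with healthy epithelium was 0.013 for AOM-DSS and -0.001 for APC-KRAS tumours.

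Few of the shared tumour genes also moved in healthy epithelium. Of those 15305 genes, 13 were called higher and 21 lower in both tumour models with an unadjusted p under 0.05 in the same direction in healthy epithelium, while 26 and 13 moved the opposite way there. An unadjusted edgeR p under 0.05 was common in healthy epithelium, at 3242 of 16870 genes. The same direction was no more frequent than the opposite one, so these counts show no shared direction with healthy epithelium. The genes named next had the smallest p there among those of the same direction. Myo18b, an unconventional myosin, had log2 changes of 3.96, 4.33 and 3.33 in AOM-DSS tumours, APC-KRAS tumours and healthy epithelium. It stood at 6.77 ± 1.6, 4.01 ± 0.89 and 3.69 ± 0.75 CPM in knockout and 0.41 ± 0.04, 0.20 ± 0.09 and 0.37 ± 0.17 CPM in wild type (SD, n = 5, 4 and 3 against 5, 5 and 3). Its edgeR adjusted p was 6.22e-05, 0.00128 and 0.0834. Rgcc, a regulator of the cell cycle, had log2 changes of -3.77, -3.81 and -2.31 (adjusted p = 0.000181, 0.00441 and 0.081), and Lgr5 of -4.60, -4.96 and -3.01. Without healthy wild-type library 3 Myo18b (3.05) and Rgcc (-2.33) passed in healthy epithelium too (adjusted p = 0.0428 for each, from 4.25e-13 to 0.316 and from 6.09e-18 to 0.316 over their alternatives).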
